A study of Synechococcus elongatus PCC 7942 = FACHB-805 with 8 samples.

How the data were processed

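The series measured RNA from the cyanobacterium Synechococcus elongatus in 8 libraries. Per the labels, both strains lacked the cell's own rel gene, which encodes the enzyme that makes and breaks down the alarmone ppGpp. The columns of the deposited values write spoT- where the sample titles write rel-, and were matched by strain, replicate and time. Each strain carried an introduced relA, the ppGpp synthetase of Escherichia coli, either intact (here the relA strain) or with the substitution E335Q (here the E335Q strain), a form used as an inactive control. Cultures grown at 30 °C and 40 µE were entrained by 2 cycles of 12 h dark and 12 h light, released into constant light and harvested at subjective dawn (circadian time 0 h) or subjective dusk (12 h). There were 4 groups with 2 libraries each.

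Per the labels' protocols, external RNA standards were present in the lysis buffer, ribosomal RNA was depleted with Ribo-Zero, libraries were made with a stranded TruSeq kit and libraries were sequenced on an Illumina HiSeq. Reads were aligned with Bowtie 0.12.7, per the submitters' processing notes. The genome build, the counting of reads per gene and the amount of culture per extraction were not given in the sources used here. The deposited table holds 1 non-negative signal value per gene and library, scaled by the authors. How that scaling was computed is not given in the sources used here, and the reads of the external standards were not analysed here.

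In each library 100% of the values were whole multiples of a single step, within a tolerance of 0.01 step. The step was taken as the value of 1 read, which gave depths of 9.32, 14.0, 10.4 and 10.6 M reads (M for mega) for relA dawn replicates 1 and 2 and dusk replicates 1 and 2. The E335Q libraries in the same order had 11.6, 10.8, 9.39 and 11.7 M reads. The median gene had from 787 to 1188 reads, so the spread between replicates and not counting error limited most comparisons. The table has 2715 named loci and 8 entries with neither ID nor name, which held at most 0.0258% of the values of a library and were left out.

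Loci are given by their tags as deposited. The table pairs no tag with a gene name, and 0 of its IDs matched the 2785 genes of the reference table used here (a RefSeq assembly of the same strain). Gene names therefore come from lists written by locus tag, from knowledge of this strain, before the data were examined. They cover 43 loci, each given with its tag at first mention, and neither the deposited table nor the reference table can check them. Of 22 lists planned, 10 had locus numbers and a plasmid list was formed from the tags with the letter B. The 10 lists were also planned with members by symbol and product, which could not be matched, so they hold only their numbered loci. Photosystem II is thus copies of psbA and psbD alone, the chaperone list holds no protease, and purine synthesis is purF alone. Results for a list do not speak for its whole pathway. The other lists (among them ribosomal proteins) needed product names and could not be formed. A list of 53 tags with the letter R, called structural RNA tags here, was added after the data were seen in place of a planned list of ribosomal and transfer RNA that needed product names.

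Values were tested as log2(value + 21.8), where the pseudocount is 1% of the median gene mean (2180.0), so fold changes are on that scale and understate the changes of low genes. Loci with a mean of at least 109 (5% of that median) were kept, which left 2610 loci and removed 105. The test was limma 3.58.1 with a mean-variance trend in R 4.3.3, on group means over all 8 libraries with 4 residual degrees of freedom, two-sided, with Benjamini-Hochberg adjustment over the loci tested and a threshold of 0.05. The comparisons were relA against E335Q at dawn and at dusk, dusk against dawn in each strain, and the interaction. No further scaling was applied, because the labels name external standards. Since the overall level differed between strains, each comparison is also given on a relative scale, in which every library was centred on its median locus. On the deposited scale most of the error was library scale shared by all loci, limma drew the spread of every locus fully to the common trend, and a locus with widely spread replicates can pass. The prior degrees of freedom were infinite there, so deposited p-values did not rest on the 4 residual ones alone. They take an error shared by all loci as known exactly and can be far too small. The deposited genotype counts largely restate the difference in level between the strains. On the relative scale the spread of single loci counts.

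Lists with at least 3 tested loci (8 per comparison) were tested with limma's camera at a preset correlation of 0.01, adjusted over the 8 lists, and again with an estimated correlation. Both used the deposited scale, where library scale shared by all loci enters the estimated correlation of any list. Library totals were compared by exact two-sided permutation tests. The named loci are the clock loci, psbAI and purF, up to 4 members per list and comparison with the largest change past the threshold, or the 2 of highest mean where none passed, and 2 rises and 2 falls by ID. Those by ID are the largest among loci past the threshold with both libraries of a group above or below both of the other. For the interaction no such separation was asked. Other members of a list are printed where they are the exception. The plan also took the loci with the largest changes by symbol, which the missing names did not allow, so the choice of IDs was made after the data were seen. Copies of psbA and of psbD are related in sequence to differing degrees, so their values are uncertain where reads could be shared.

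The methods were tested on reads simulated from the overall mean of each locus with the spread seen between replicates. With 2-fold changes planted in 66 or 67 loci, limma recovered 48.5% at dawn, 71.2% at dusk, 47.0% for time in relA, 1.49% for time in E335Q and 17.9% for the interaction on the deposited scale. On the relative scale it recovered 92.5%, 92.5%, 88.1%, 95.5% and 45.5%. All groups were simulated with the same spread, and the deposited scale with a single draw of library scales per comparison. The deposited figures depend on that draw and do not rank the comparisons. The alternatives were a replicate block, the 4 libraries of a comparison alone, centring, quantile normalization, other filters and pseudocounts, no trend, a 2-fold minimum, no structural RNA tags, and leaving out each library. Figures were drawn with matplotlib 3.10.9.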

Results

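The 8 libraries fell into 4 groups of 2, from the relA and E335Q strains at subjective dawn and at subjective dusk. Depth ranged from 9.32 to 14.0 M reads. All values are deposited values (no unit) as mean ± SD with n = 2, and log2 changes are relA minus E335Q or dusk minus dawn. Nothing in the labels says that replicates were separate cultures, so p-values measure the spread between these samples. Gene names stand for locus tags assigned from knowledge of the strain and were not paired with the tags by the deposited table.

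The deleted gene was examined first. The rel locus (Synpcc7942_1377) had 9, 1, 5 and 20 reads in the relA libraries (dawn 1 and 2, dusk 1 and 2) and 6, 0, 0 and 12 in the E335Q libraries. The highest of these was 2.14% of its library's median locus. The introduced relA was not analysed here.

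The deposited values were lower in the relA strain than in E335Q at nearly every locus. The median locus was 2.75-fold lower in the relA strain at dawn (median log2 change -1.46) and 3.13-fold lower at dusk (-1.65). At dawn 97.0% of loci were lower and at dusk 98.0%. Library sums were 12.2 ± 0.275 M in relA against 35.7 ± 9.57 M in E335Q at dawn, and 11.6 ± 0.402 against 37.3 ± 2.20 M at dusk. The read depths did not differ in this way, with means of 11.1 ± 2.04 M in relA and 10.9 ± 1.09 M in E335Q (n = 4).

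In exact two-sided permutation tests of the sums, each time gave p = 0.33, the smallest that 2 against 2 libraries allow. Pooled over both times, 4 against 4 libraries gave exact permutation p = 0.0286, the smallest of 70 regroupings, in a test added after the shift was seen. The regroupings did not keep dawn and dusk apart and took all libraries as independent, which the labels do not state. The small p rests on that pooling. The E335Q dawn libraries differed 1.54-fold in scale, and the dawn shift was -1.13 without replicate 1 and -1.77 without replicate 2. Between dusk and dawn the sums gave exact p = 0.33 in relA and p = 1 in E335Q.

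**Figure D1:**
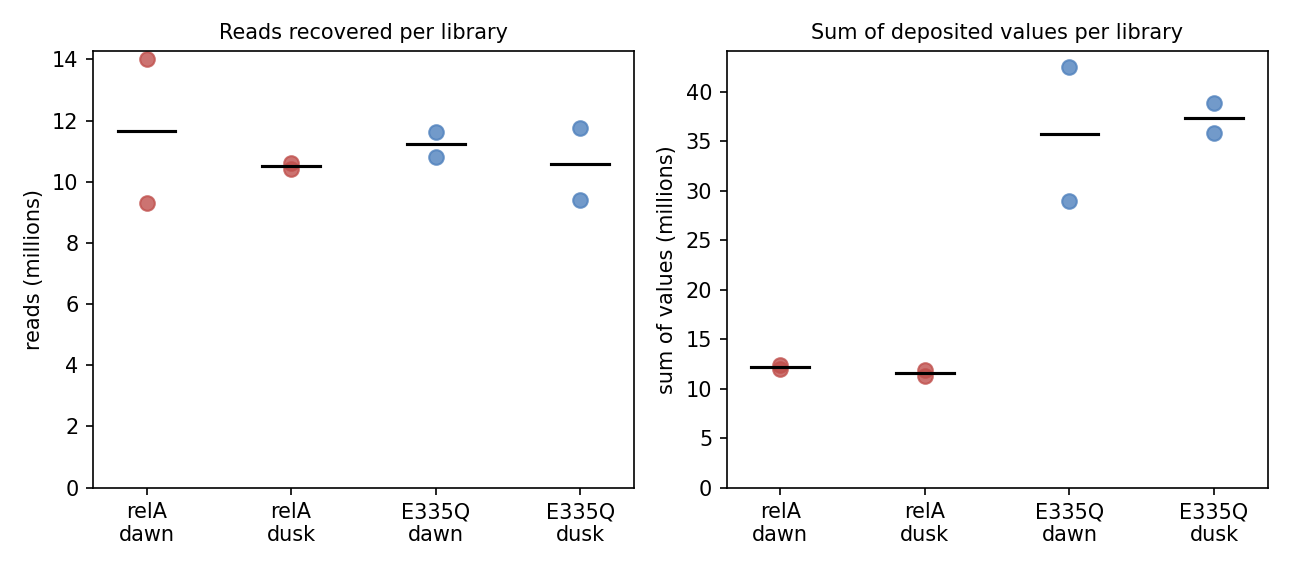
Reads recovered per library (left, M) and sums of the deposited values per library (right, M) for the 4 groups, with 1 point per library and lines at the means of 2. Sums lay between 11.3 and 12.4 M in relA and between 29.0 and 42.5 M in E335Q, while reads overlapped.

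The comparison of the strains at subjective dawn asks which transcripts differ with the active synthetase at that time. As deposited, the loci of the clock, the sigma factors and glycogen and pentose phosphate metabolism were lower in relA, as nearly all loci were, and relative to the library medians most of them did not pass. Against the other loci the nitrogen assimilation and plasmid lists were less reduced and the chaperones more, by limma's camera, although none of the 3 passed with an estimated correlation. narB (Synpcc7942_1235, nitrate reductase) was 2.76-fold higher in relA, at 1310.1 ± 384 against 515 ± 361, a fold of 4.66 without E335Q dawn replicate 1 and 1.65 without replicate 2. The chaperonin groEL2 (Synpcc7942_0685) was 4.81-fold lower, at 7188 ± 401 against 34829 ± 5249.

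By limma, 34 loci were higher and 2336 lower at adjusted p under 0.05, and relative to the library medians 1162 passed, of which 518 were higher and the others lower. The relative changes fell with the level of the loci, from a median of 0.22 in the lowest to -0.22 in the highest of 5 groups split by their centred level at dusk (0.17 and -0.20 with a pseudocount of 0.1%), and those of single loci are not adjusted for it. All 10 clock loci were lower (10 adjusted over the list alone). kaiC (Synpcc7942_1216, the central clock ATPase) had a log2 change of -1.21 (SE 0.26), which turned to 0.21 relative to the library median without passing there. On the relative scale, pex (Synpcc7942_0677, period extender) and rpaA (Synpcc7942_0095, a clock output regulator) were higher and ldpA (Synpcc7942_0624) lower, at 0.68, 0.39 and -0.40. As deposited these 3 stood at -0.74, -1.03 and -1.82, so pex and rpaA change direction with the scaling. All 4 sigma factor loci were lower (4 adjusted over the list alone), among them rpoD1 (Synpcc7942_0649, the principal sigma factor) at -1.45, and relative to the medians 1 was higher and 1 lower.

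All 5 chaperone loci were lower (5 adjusted over the list alone), and 4 remained lower relative to the library medians. Those were groES (Synpcc7942_2314) at -0.83, groEL2 at -0.85, dnaK2 (Synpcc7942_2468) at -0.82 and groEL1 (Synpcc7942_2313) at -0.68. The list was low against the other loci by limma's camera at adjusted p = 0.0191 (adjusted p = 0.482 with an estimated correlation), a call lost without relA dawn replicate 2 (adjusted p = 0.0543) or E335Q dawn replicate 1 or 2 (0.187 and 0.733), after centring or after quantile normalization. Of 6 nitrogen assimilation loci, 2 were higher, 1 lower and 3 did not pass (the same counts adjusted over the list alone), and 5 were higher relative to the medians. glnA (Synpcc7942_2156, glutamine synthetase) stood at -0.35 as deposited and 1.07 relative to the median, the latter past the threshold. The list's median was -0.19 as deposited, while camera placed it above the other loci at adjusted p = 1.34e-06 by limma (adjusted p = 0.313 with an estimated correlation).

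nrtA (Synpcc7942_1239, nitrate transporter binding protein) was called higher at 1.41, but its E335Q dawn libraries held 51444 and 2999 and enclosed both relA libraries. The deposited-scale test uses a spread common to all loci, so such a locus can pass. Without E335Q dawn replicate 2 it was called lower, at -0.64 (limma adjusted p = 0.0412), and without replicate 1 its change was 3.45. These gave 1.09 and 4.56 relative to the medians. There the change of 2.83 lost its call without either relA dawn library (2.91 and 2.74).

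All 6 loci of glycogen and the oxidative pentose phosphate route were lower (6 adjusted over the list alone). An example was glgC (Synpcc7942_0603, ADP-glucose pyrophosphorylase) at -1.60, whereas glgB (Synpcc7942_1085, branching enzyme) was -0.87 as deposited and turned to 0.55, past the threshold, relative to the medians. Of 5 photosystem II loci 3 were lower (3 adjusted over the list alone). psbAI (Synpcc7942_0424, a D1 protein gene with other copies) did not pass as deposited at 0.25, and passed at 1.67 relative to the median. Also lower were rbcL and rbcS (Synpcc7942_1426 and Synpcc7942_1427, Rubisco) at -1.46 and -1.25, hpf (Synpcc7942_2352, ribosome hibernation) at -1.15, isiA and isiB (Synpcc7942_1542 and Synpcc7942_1541) at -1.11 and -1.46, and purF (Synpcc7942_0004, purine synthesis) at -1.72. Of these rbcS, hpf and isiA turn positive relative to the medians (0.17, 0.26 and 0.31), where none of the 3 passed, and purF stayed lower at -0.30.

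Among 15 plasmid loci that passed the filter, of 50 in the table, 3 were higher and 2 lower (2 and 1 adjusted over the list alone), and 13 were higher relative to the medians. The plasmid median was -0.39 as deposited and turned to 1.03 relative to the library medians, with camera at adjusted p = 1.91e-10 by limma (adjusted p = 0.283 with an estimated correlation). Of 32 structural RNA tags 31 were lower, with a median of -1.06 that turned to 0.36 relative to the medians. Ribosomal RNA was depleted from the libraries, so any ribosomal tags among them also depend on that step, which was not tested. The clock, sigma factor, photosystem II, glycogen and structural RNA lists did not pass camera (limma adjusted p from 0.0687 to 0.746). The largest changes by ID were Synpcc7942_1607 (30.6-fold) and Synpcc7942_2038 (7.29-fold) higher in relA, and Synpcc7942_2126 (12.3-fold) and Synpcc7942_1490 (12.1-fold) lower. Without relA dawn replicate 1 or 2 or E335Q dawn replicate 1 or 2 the fold of Synpcc7942_2126 was 19.6, 7.69, 6.95 and 22.0. Photosystem II and the structural RNA tags passed camera as less reduced without relA dawn replicate 2 (limma adjusted p = 0.0359 and 0.000127), E335Q dawn replicate 1 (0.00214 and 4.28e-07) or replicate 2 (0.00209 and 2.15e-08).

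As deposited, 4 of the loci followed lost or reversed their call without a library. They were nrtA, pex (-0.62 without relA dawn replicate 1), psbDI (Synpcc7942_0655, -0.14 without E335Q dawn replicate 1, -0.47 without relA dawn replicate 2) and psbDII (Synpcc7942_1637, -0.67 without E335Q dawn replicate 1). Without E335Q dawn replicate 2 psbDI and psbDII kept their calls, at -1.61 and -2.19. psbAI passed at 0.49 without E335Q dawn replicate 1. Among the relative changes, 11 of 44 lost theirs. Beside nrtA they were rpaA (0.26 without relA dawn replicate 2, 0.34 without E335Q dawn replicate 2), ldpA (-0.24, -0.38 and -0.42 without relA dawn replicate 2, E335Q dawn replicate 1 or 2), groEL1 (-0.66, -0.70 and -0.34 without relA dawn replicate 1 or 2 or E335Q dawn replicate 2) and purF (-0.27 to -0.32 without any 1 of the dawn libraries). The others were nirA (1.40 and 1.36 without relA dawn replicate 1 or 2), nblA (Synpcc7942_2127, 0.63 without relA dawn replicate 1), Synpcc7942_1746 (-0.25 to -0.53 without relA dawn replicate 2, E335Q dawn replicate 1 or either relA dusk library), Synpcc7942_1849 (0.26 to 0.50 without any 1 relA library or E335Q dawn replicate 2), glgA (Synpcc7942_2518, 0.22 to 0.42 without the same 5) and Synpcc7942_1490 (-2.08 without relA dawn replicate 2). Leaving out relA dawn replicate 2 gave a relative count of 750. Fitting the 4 dawn libraries alone ended the deposited calls of pex and psbDI and the relative calls of rpaA, ldpA, purF, Synpcc7942_1746, Synpcc7942_1849 and glgA. Relative calls also ended with a pseudocount of 10% for rpaA (0.26) and glgA (0.31) or of 0.1% for Synpcc7942_1849, with no trend for Synpcc7942_1746 and glgA, with the strict filter for the former, and with the replicate block or no filter for glgA.

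At subjective dusk nearly all deposited values were again lower in relA, and 19 of the 31 loci that were higher in relA at dusk were also higher at dawn. The clock loci, 3 of 4 sigma factor loci and the chaperonins were lower in relA, while hpf did not pass, at 19627 ± 3589 against 22167 ± 6126. kaiC was 3.91-fold lower, at 10151 ± 679 against 39787 ± 2646. narB, higher in relA at dawn, was 2.12-fold lower at dusk (2004 ± 350.0 against 4268 ± 656). Relative to the median its change was 0.54, which did not pass except as higher with the 4 dusk libraries alone.

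By limma, 31 loci were higher and 2469 lower, and relative to the library medians 436 were higher and 517 lower. From the lowest to the highest of 5 groups split by level at dawn the median relative change ran from 0.18 to -0.13 (0.09 to -0.12 with a pseudocount of 0.1%). All 10 clock loci were lower (10 adjusted over the list alone), and relative to the medians 2 were higher and 2 lower. cikA (Synpcc7942_0644, a clock histidine kinase) had -0.82 as deposited and 0.81 relative to the median, and pex -0.68 and 0.95, so both change direction with the scaling and pass on each scale. ldpA stayed lower at -2.31 and -0.68. kaiC was -0.34 relative to the median, and that call was lost without relA dusk replicate 1 (-0.21), either relA dawn library (-0.34, -0.34) or either E335Q dusk library (-0.41, -0.27).

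Of 5 chaperone loci 4 were lower (4 adjusted over the list alone) and hspA (Synpcc7942_2401) did not pass at -0.40. Once centred, groES (-0.60) and groEL2 (-0.44) passed, and both lost the call without any 1 of relA dusk replicates 1 and 2 and E335Q dusk replicate 1 (groES -0.48 to -0.60, groEL2 -0.35 to -0.50). The list's median was -2.06 and it did not pass camera at limma adjusted p = 0.342. Of 4 sigma factor loci 3 were lower (3 adjusted over the list alone), with the alternative sigma factor locus Synpcc7942_1849 at -0.22 without passing and at 1.40, past the threshold, relative to the median. hpf, at -0.16, did not pass as deposited and was higher at 1.47 relative to the median.

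Of 6 nitrogen assimilation loci 5 were lower (5 adjusted over the list alone), and 2 were higher relative to the medians. Those were glnA, at -0.69 as deposited and 0.94 relative to the median, and nirA (Synpcc7942_1240, nitrite reductase), at -0.32 without passing and 1.31. The glnA call was lost as deposited without relA dusk replicate 1 or 2 or E335Q dusk replicate 1 (-0.65, -0.73 and -0.50) and on the relative scale without relA dusk replicate 2 (0.84). The relative nirA call was lost without relA dusk replicate 1 or 2 or E335Q dusk replicate 2 (1.30, 1.32 and 0.91). All 6 glycogen and pentose phosphate loci were lower (6 adjusted over the list alone), for example zwf (Synpcc7942_2334, glucose-6-phosphate dehydrogenase) at -1.35 and glgP (Synpcc7942_0244, glycogen phosphorylase) at -1.26, and both turn positive relative to the medians (0.28 and 0.37) without passing. zwf passed there with the strict filter (0.29), a pseudocount of 0.1% (0.29) or no structural RNA tags (0.28). opcA passed with the strict filter (0.37), the 4 dusk libraries alone (0.36) or no structural RNA tags (0.36). glgA and glgC were higher relative to the medians (0.43 and 0.42), against -1.20 and -1.21 as deposited.

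Of 5 photosystem II loci 2 were lower (2 adjusted over the list alone), among them psbAI at -1.27, and 2 were higher relative to the medians (4 adjusted over the list alone). psbAI stood there at 0.36, a call lost without any 1 relA dusk or E335Q library (0.34 to 0.38), with the replicate block, no filter or no trend, or with a pseudocount of 10%, where it was 0.21. Camera placed the list above the other loci at limma adjusted p = 0.0338, against adjusted p = 0.748 with an estimated correlation, although its deposited median was -0.71. That call was lost without relA dusk replicate 2 (limma adjusted p = 0.234) or E335Q dusk replicate 1 (0.0957), after centring or after quantile normalization. Of 15 plasmid loci 3 were higher and 3 lower (3 and 0 adjusted over the list alone), and all 15 were higher relative to the medians. Their median of -0.28 as deposited turned to 1.35 (limma camera adjusted p = 2.97e-17, and adjusted p = 0.121 with an estimated correlation).

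All 32 structural RNA tags were lower, with a median of -1.36 that turned to 0.27 relative to the medians, and depletion of ribosomal RNA may enter as at dawn. These tags were 2.89-fold higher at the median in E335Q dusk replicate 2 than in replicate 1 after centring, and the relative list median was -0.33 without replicate 1 and 0.97 without replicate 2, passing camera in opposite directions. The clock, sigma factor, glycogen, nitrogen and structural RNA lists did not pass camera (limma adjusted p from 0.0753 to 0.932). The nitrogen list passed as less reduced without relA dusk replicate 1 (limma adjusted p = 0.0389) or E335Q dusk replicate 1 (0.0105), and the structural RNA tags without relA dusk replicate 1 (0.00779) or E335Q dawn replicate 1 or 2 (9.25e-09 and 1.58e-09). rbcL, rbcS, isiA, isiB and purF were lower as deposited (-1.32, -0.92, -0.92, -1.28 and -1.51) and all 5 turn positive relative to the medians (0.30, 0.71, 0.71, 0.34 and 0.12), where rbcS and isiA passed. Higher by ID were Synpcc7942_2306 (9.17-fold) and Synpcc7942_2307 (7.89-fold), and lower were Synpcc7942_2126 (16.1-fold) and Synpcc7942_2124 (15.5-fold).

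Other deposited calls lost without a library were cikA (-0.73 without relA dusk replicate 2), pex (-0.65 to -0.71 without any 1 dusk library), isiA (-0.85 without relA dusk replicate 2, -0.67 without E335Q dusk replicate 1), rbcS (-0.69 without E335Q dusk replicate 1) and psbDI (-0.39 without relA dusk replicate 1, -0.11 without E335Q dusk replicate 2, -0.84 without either E335Q dawn library). Without E335Q dusk replicate 1 psbDI kept its call, at -1.56. Relative calls of rbcS (0.54 without relA dusk replicate 2, 0.49 without E335Q dusk replicate 2) and isiA (0.46, 0.70 and 0.72 without E335Q dusk replicate 2 or relA dusk replicate 1 or 2) were lost as well. So were those of glgC (0.32, 0.49 and 0.35 without relA dusk replicate 2 or E335Q dusk replicate 1 or 2), glgA (0.31 to 0.55 without any 1 relA or E335Q dusk library), psbAII (Synpcc7942_0893, 0.79 and 0.82 without relA or E335Q dusk replicate 2) and Synpcc7942_1746 (-0.78 and -0.79 without relA dusk replicate 1 or 2). The relative calls of kaiC (replicate block, strict filter, pseudocount of 0.1%, no trend, 4 libraries alone), glgA (no filter, no trend, pseudocount of 10%), glgC (pseudocount of 10%) and psbAII (pseudocount of 0.1%) also ended under other settings, as did the deposited psbDI call with the 4 dusk libraries alone. Some named loci instead gained a relative call when a library was left out, at dusk as at dawn. The relative count fell from 953 to 549, 554, 628 and 635 without relA dusk replicates 1 and 2 and E335Q dusk replicates 1 and 2.

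**Figure D2:**
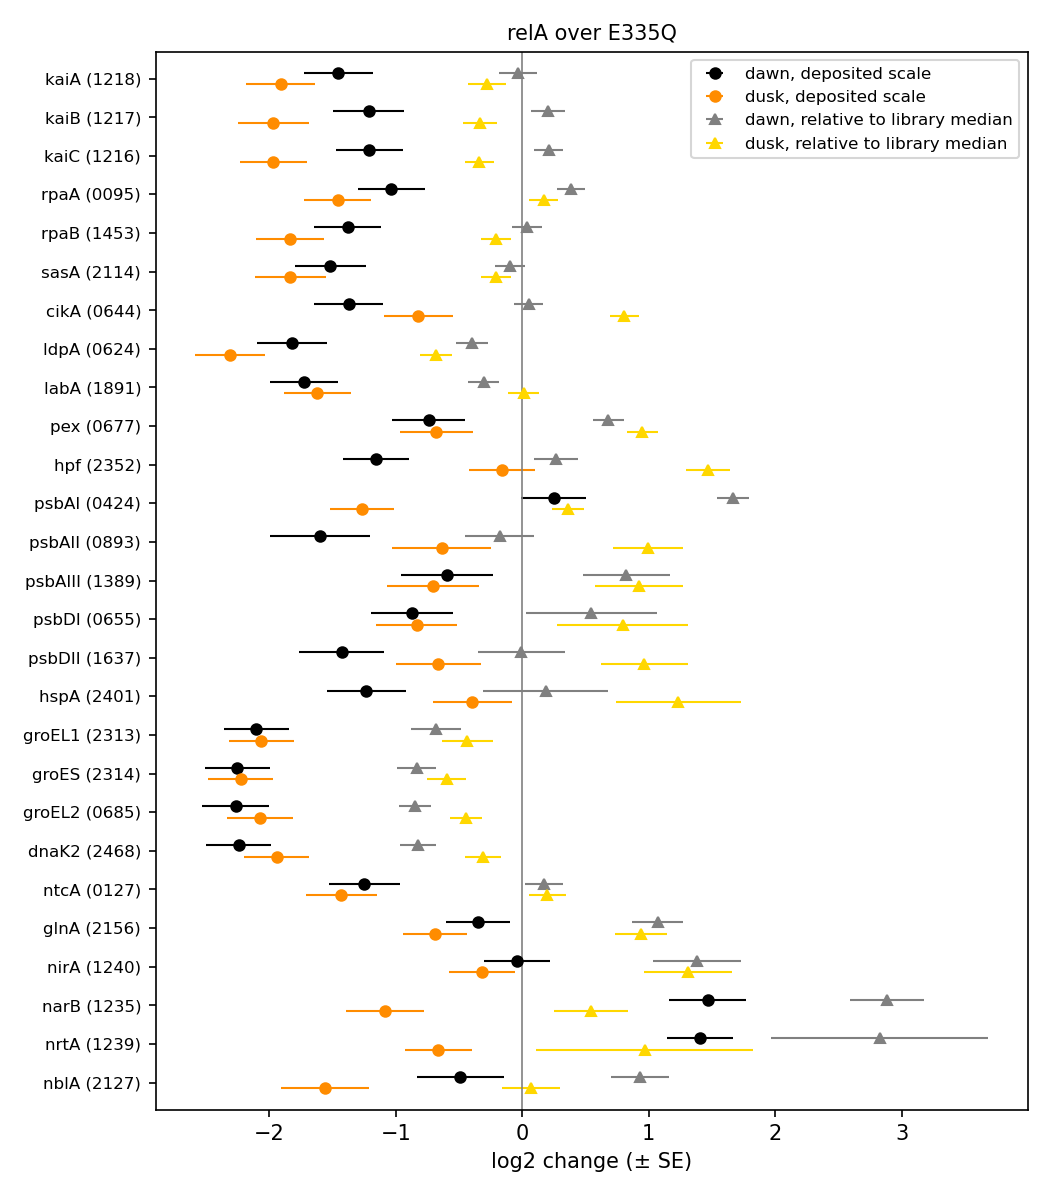
Log2 changes of relA over E335Q (x axis, ± SE) for named loci at dawn and dusk, as deposited (circles) and relative to the library median (triangles). The 5 chaperone loci, clock loci such as kaiC (-1.21 and -1.97) and most others lie left of 0 as deposited, and many including pex, cikA and glnA lie right of 0 once centred.

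**Figure D3:**
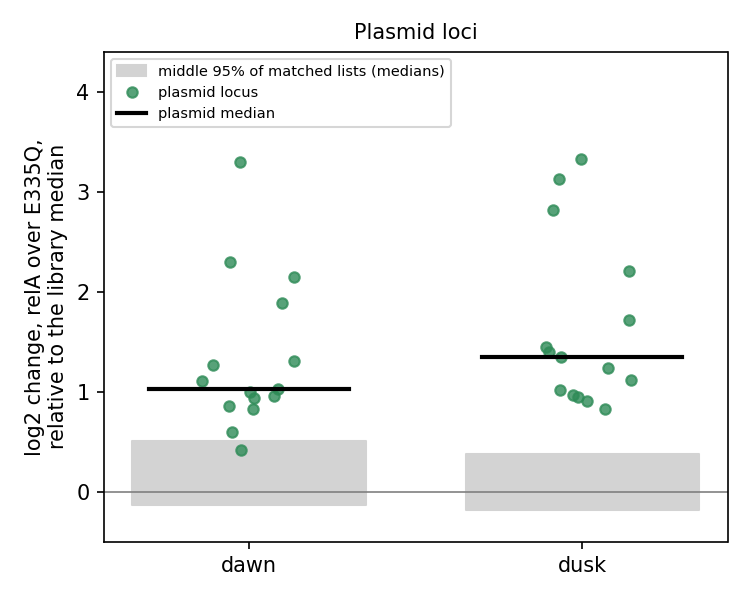
Log2 changes of relA over E335Q relative to the library median (y axis) for 15 plasmid loci at dawn and at dusk, with the plasmid median (line) and the central range of the medians of 10000 chromosomal lists matched on mean value (grey). The plasmid medians of 1.03 and 1.35 lie above the grey ranges of -0.13 to 0.51 and -0.18 to 0.38, although as deposited they are below 0 at -0.39 and -0.28.

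The genotype effects at dawn and dusk, from separate libraries, were compared next. On the relative scale, 214 loci were higher in relA at both times, where independent lists would share 86.5, and 309 were lower, where 128 would be shared. As deposited 2275 were lower at both times (2210 for independent lists) and 19 higher (0.404). Of the loci higher at dawn on the relative scale 27 were called lower at dusk, and of those lower at dawn 22 were called higher. Both comparisons used the same estimate of each locus's spread, so low-spread loci can pass in both and the calls are not independent. Across loci, which are not independent replicates, the changes correlated with Pearson r = 0.57 and Spearman rho = 0.52.

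Dusk was compared with dawn in the relA strain, to see which transcripts differ between these times while the synthetase is active. Loci of glycogen breakdown and the pentose phosphate route were among the largest rises of the named loci. zwf rose 10.3-fold from 875 ± 5.80 to 9218 ± 1113, opcA (Synpcc7942_2333, its activator) 9.36-fold and glgP 5.89-fold. The alternative sigma factor locus Synpcc7942_1849 rose 49.1-fold, from 307 ± 3.99 to 16177 ± 1709. Rubisco loci, purF and 3 of 6 nitrogen assimilation loci fell.

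By limma 231 loci rose and 180 fell, and relative to the library medians 421 rose and 609 fell. Of 10 clock loci 2 rose and 8 did not pass (4 rose adjusted over the list alone). They were kaiC at 1.09 and cikA at 1.21. Once centred, 4 rose, with kaiB (Synpcc7942_1217) at 0.73 and pex at 0.72 joining them, and labA (Synpcc7942_1891) and rpaB (Synpcc7942_1453) fell at -0.54 and -0.44. kaiA (Synpcc7942_1218), sasA (Synpcc7942_2114), rpaA and ldpA passed on neither scale, at -0.14, -0.06, 0.07 and -0.12. hpf rose at 0.95.

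Of 6 glycogen and pentose phosphate loci 3 rose and 3 did not pass (3 rose and 1 fell adjusted over the list alone), and glgC fell on the relative scale at -0.67. The list passed limma's camera at adjusted p = 3.94e-05 (adjusted p = 0.403 with an estimated correlation). The sigma factor list passed at adjusted p = 0.000199 (adjusted p = 0.403 with an estimated correlation), although only 1 of its 4 members, Synpcc7942_1849, rose (1 adjusted over the list alone). Of 6 nitrogen assimilation loci 3 fell and 3 did not pass (4 fell and 1 rose adjusted over the list alone). ntcA (Synpcc7942_0127, the nitrogen regulator) fell at -1.19, nirA at -1.29 and nrtA at -1.41, and the list passed limma's camera at adjusted p = 0.0377 (adjusted p = 0.643 with an estimated correlation). Without E335Q dawn replicate 1 or 2 these 3 list calls were lost (limma adjusted p = 0.0807 and 0.101 for sigma factors, 0.103 and 0.104 for each of the others), and the nitrogen call also without relA dawn replicate 2 (0.0619) or relA dusk replicate 1 (0.0516). After centring or quantile normalization none of the 3 lists passed camera. On the relative scale limma's fry gave unadjusted p = 3.47e-05 for the glycogen list and 0.000335 for the sigma factors, both as rises. For nitrogen assimilation fry gave unadjusted p = 0.0517, as a fall. With libraries centred, the nrtA change of -1.40 did not pass.

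Of 5 chaperone loci groEL1 and groES rose, at 0.93 and 1.08, and 3 did not pass (3 rose adjusted over the list alone). rbcL fell at -0.97, rbcS at -0.79 and purF at -1.10. None of the 5 photosystem II loci, of isiA and isiB or of the 32 structural RNA tags passed on either scale (0 adjusted over each list alone), and psbAI stood at 0.33. Of 15 plasmid loci 4 rose (5 adjusted over the list alone). The clock, photosystem II, chaperone, plasmid and structural RNA lists did not pass camera (limma adjusted p from 0.0871 to 0.875), except the chaperones without relA dawn replicate 1 (adjusted p = 0.0271). By ID the largest rise beside Synpcc7942_1849 was Synpcc7942_0834 (64.6-fold), and the largest falls were Synpcc7942_1607 (44.0-fold) and Synpcc7942_0840 (11.3-fold).

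The count of 411 calls was 193 and 186 without relA dawn replicates 1 and 2, 173 and 215 without relA dusk replicates 1 and 2, and 1057 without either E335Q dawn library, which enter through the shared spread. The split into rises and falls moved with it, from 231 and 180 to 153 and 40, 139 and 47, 132 and 41, and 166 and 49 without those relA libraries, and to 417 and 640 without either E335Q dawn library. Calls lost as deposited were kaiC (1.03 and 1.03 without relA dawn or dusk replicate 2), cikA (1.12 without relA dusk replicate 1), ntcA (-1.11 without relA dusk replicate 1), purF (-1.05 without relA dawn replicate 1), groES (1.05 and 1.01 without relA dawn or dusk replicate 1), hpf (0.76 to 0.98 without relA dawn replicate 1 or 2 or dusk replicate 1), and groEL1, rbcL and rbcS without any 1 relA library (groEL1 0.92 to 0.95, rbcL -1.01 to -0.93, rbcS -0.91 to -0.68). On the relative scale, where the count was 585 without relA dusk replicate 1 and 683 without relA dawn replicate 2, rpaB (-0.31 without relA dawn replicate 2, -0.41 and -0.48 without relA dusk replicate 1 or 2), labA (-0.48 without relA dusk replicate 1), rbcS (-0.64 and -0.60 without relA dawn replicate 2 or dusk replicate 1), nirA (-1.30 to -1.26 without any 1 relA library) and glnA (-0.77 to -0.51 without any 1 relA library) lost their calls. The deposited rbcS call also ended with no trend, and with a pseudocount of 10% the folds of Synpcc7942_1849, Synpcc7942_0834 and Synpcc7942_1607 were over 1.5 times smaller. Without either E335Q dawn library kaiB (0.72), pex (0.71), rpaB (-0.46) and labA (-0.56) passed as deposited and nrtA (-1.40) on the relative scale, as did psbAI (0.47) without relA dawn replicate 2.

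The same comparison in the E335Q strain shows the dusk and dawn states with the substituted synthetase. The same loci of glycogen breakdown and the pentose phosphate route rose, zwf 11.1-fold from 2133 ± 642 to 23459.5 ± 955, opcA 10.7-fold and glgP 6.75-fold. Synpcc7942_1849 rose 29.4-fold, kaiC 3.61-fold and psbAI 3.59-fold. narB rose 9.03-fold, from 515 ± 361 to 4268 ± 656 (15.3-fold without E335Q dawn replicate 1, 5.39-fold without replicate 2).

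By limma 384 loci rose and 105 fell, and relative to the library medians 482 rose and 762 fell. Of 10 clock loci kaiB and kaiC rose, at 1.48 and 1.85, and 8 did not pass (4 rose and 1 fell adjusted over the list alone). Once centred, cikA (0.47) and pex (0.46) rose as well and labA fell (-0.86). kaiA (0.31), rpaA (0.49), sasA (0.26) and ldpA (0.37) passed on neither scale, nor did rpaB, which was -0.00359 as deposited and -0.20 relative to the median. hpf stood at -0.04 and did not pass on either scale.

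Of 6 glycogen and pentose phosphate loci 3 rose, glgC fell at -1.07 and 2 did not pass (4 rose and 1 fell adjusted over the list alone). The list passed limma's camera at adjusted p = 0.000108 (adjusted p = 0.451 with an estimated correlation), and the sigma factor list at adjusted p = 0.0026 (adjusted p = 0.451 with an estimated correlation). Of its 4 members Synpcc7942_1849 and rpoD1 (0.69) rose (2 adjusted over the list alone). Both list calls were lost without E335Q dawn replicate 1 (limma adjusted p = 0.222 for each) or replicate 2 (0.0622 for each) and after centring, and kept after quantile normalization. On the relative scale limma's fry gave unadjusted p = 3.36e-05 for the glycogen list and 0.000107 for the sigma factors, both as rises. Of 6 nitrogen assimilation loci narB rose, ntcA and nirA fell (-1.01 and -1.01) and 3 did not pass (3 rose and 2 fell adjusted over the list alone). The nitrogen list's median was 0.17 as deposited and -0.03 relative to the library medians, with a relative mean of 0.18.

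groEL1 and groES rose at 0.89 and 1.05, while 3 chaperone loci did not pass (2 rose adjusted over the list alone). rbcL fell at -1.10, rbcS at -1.13 and purF at -1.31. Of 5 photosystem II loci psbAI alone passed as deposited (1 rose and 1 fell adjusted over the list alone on either scale). No plasmid locus, structural RNA tag, isiA or isiB passed as deposited (0 adjusted over each list alone), and relative to the medians 1 plasmid locus rose and 1 structural RNA tag fell. The clock, photosystem II, chaperone, nitrogen, plasmid and structural RNA lists did not pass camera (limma adjusted p from 0.32 to 0.937). The structural RNA tags passed with a relative median of 0.78 without E335Q dusk replicate 1 and -0.76 without replicate 2. By ID the largest rises were Synpcc7942_0304 (34.5-fold) and Synpcc7942_1612 (33.5-fold), and the largest falls Synpcc7942_0839 (6.19-fold) and Synpcc7942_0840 (6.06-fold).

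The direction of the overall count rested on the E335Q dawn libraries. Without replicate 1 there were 1213 calls, 1079 of them rises, and without replicate 2 there were 1158, of which 816 were falls, while E335Q dusk replicates 1 and 2 left out gave 283 and 271. Calls lost were rpoD1 (0.68 to 0.70 without any 1 relA or E335Q dusk library), nirA (-0.12 and -1.90 without E335Q dawn replicate 1 or 2, the latter kept, -0.60 without E335Q dusk replicate 2), rbcL, rbcS and ntcA without E335Q dusk replicate 2 (-0.88, -0.90 and -0.81), glgC without that library (limma adjusted p = 0.0513), and groEL1 and groES without E335Q dusk replicate 1 (0.79 and 0.93). Among the relative changes, cikA (0.43 without E335Q dusk replicate 2) and pex (0.41 without E335Q dawn replicate 1, 0.42 without E335Q dusk replicate 2) lost theirs, as did nirA (-0.63 and -0.81 without E335Q dawn replicate 1 or dusk replicate 2), groEL1 (0.37 and 0.60 without E335Q dawn or dusk replicate 1), psbAII (-0.96) and glgB (0.34) without E335Q dusk replicate 2, and glgA (-0.43 to -0.24 without any 1 relA library, E335Q dawn replicate 1 or dusk replicate 2). Without E335Q dawn replicate 1 kaiA, rpaA, sasA, ldpA, cikA, labA and pex passed as deposited (0.45, 0.85, 0.66, 0.70, 0.85, -0.51 and 0.91), and without replicate 2 cikA, labA and isiB did (0.49, -0.82 and -0.66). Fitting the 4 E335Q libraries alone ended the deposited calls of ntcA, glgC, rpoD1, nirA, groEL1 and groES and the relative calls of nirA, groEL1 and glgA, and dropping the trend those of rpoD1 (deposited) and glgA (relative). With libraries centred, hpf (-0.52) and isiA (-0.56) passed without E335Q dusk replicate 1, and rpaA (0.30) and isiB (-0.50) without either relA dawn library.

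**Figure D4:**
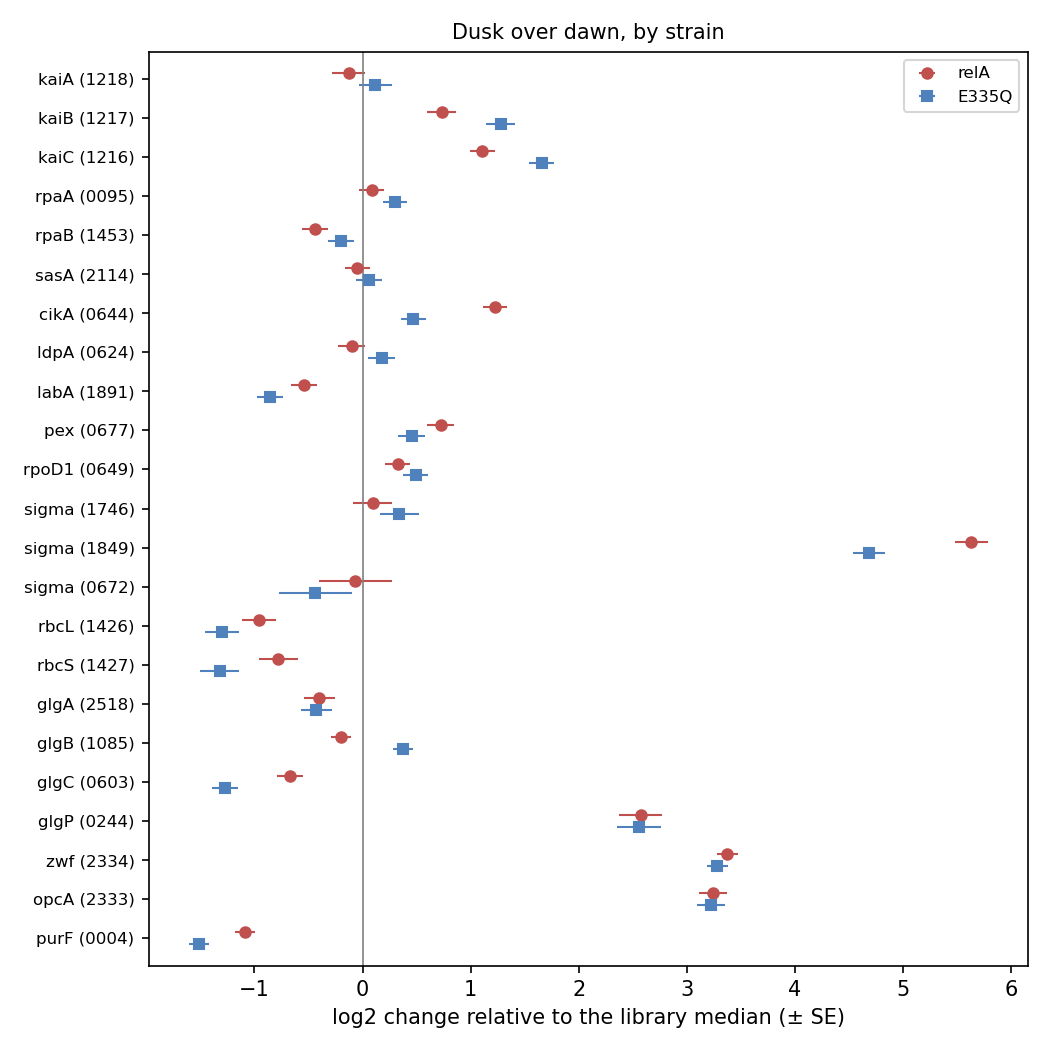
Log2 changes of dusk over dawn relative to the library median (x axis, ± SE) in relA (circles) and E335Q (squares) for named loci of the clock, glycogen and pentose phosphate, sigma factor, carbon fixation and purine lists. Synpcc7942_1849 (5.63 and 4.68), zwf (3.37 and 3.28) and kaiC (1.11 and 1.66) lie right of 0 in both strains, and rbcL and purF left of 0.

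The time effects in the strains, from separate libraries, shared more loci than independent lists would. As deposited 172 loci rose in both (34.0 for independent lists) and 52 fell in both (7.24). Once centred, 270 rose in both (77.7) and 331 fell in both (178). Of the centred rises in relA 20 were called as falls in E335Q, and of the falls 24 as rises. Here too the spread estimate of each locus was shared, so the calls are not independent. Across loci, which are not independent replicates, the changes correlated with Pearson r = 0.69 and Spearman rho = 0.54. Of the 126 to 600 calls shared when a library was left out, the lowest came without relA dusk replicate 1 and the highest without E335Q dawn replicate 2.

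The interaction tests directly whether the dusk to dawn change differed between the strains. As deposited narB and psbAI passed and no clock locus did, in a test that recovered 17.9% of simulated 2-fold differences in a single draw of library scales. narB, which rose in E335Q and did not pass in relA (0.63), had a difference of -2.55 (SE 0.43, limma adjusted p = 7.06e-07) that stood at -2.34 on the relative scale. Without E335Q dawn replicate 1 or 2 it was -3.31 or -1.80 and passed. psbAI, likewise higher at dusk in E335Q (76401 ± 18002 to 270638 ± 3706), went from 89680.1 ± 8619 to 112467 ± 6283 in relA, a difference of -1.52 (SE 0.36, limma adjusted p = 0.00182) and -1.31 on the relative scale.

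By limma 17 loci had a higher and 64 a lower time change in relA than in E335Q, and relative to the medians 199 and 214. None of the 10 clock loci passed as deposited (0 adjusted over the list alone), with kaiC at -0.76 and kaiB at -0.75. cikA alone passed relative to the medians, at 0.76, and adjusted over the list alone 1 locus was higher and 1 lower there. Under other settings kaiC passed there as lower, with the strict filter (-0.58), a pseudocount of 10% (-0.58) or no structural RNA tags (-0.55). hpf had 1.00 as deposited without passing and 1.20 relative to the medians, past the threshold. Among the relative changes, Synpcc7942_1849 (0.95), glgC (0.60) and glgB (-0.57) also passed, against 0.74, 0.39 and -0.78 as deposited. zwf (-0.12), opcA (-0.19) and glgP (-0.20) did not pass on either scale.

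Of 6 nitrogen assimilation loci narB and nrtA were lower and 4 did not pass (2 lower adjusted over the list alone), and relative to the medians narB alone passed. The list's median was -0.71 and it passed limma's camera at adjusted p = 0.00305 (adjusted p = 0.985 with an estimated correlation, and adjusted p = 0.784 without E335Q dawn replicate 2), a call lost after centring or quantile normalization. The nrtA difference of -2.07 was -4.11 without E335Q dawn replicate 1 and -0.02 without replicate 2, which held 2999 against 51444 in replicate 1. No locus of the sigma factor, glycogen, chaperone, plasmid or structural RNA lists passed as deposited (0 adjusted over each list alone), nor did rbcL (0.14), rbcS (0.33), isiA (0.18), isiB (0.18) or purF (0.21). Of 5 photosystem II loci psbAI passed (1 adjusted over the list alone). The other lists did not pass camera (limma adjusted p from 0.203 to 0.961). The chaperones and plasmid loci passed without E335Q dawn replicate 1 (limma adjusted p = 0.0431 for each), and the structural RNA tags without relA dawn replicate 2 (relative median -0.34) or E335Q dusk replicate 1 or 2 (-0.78 and 0.80). By ID Synpcc7942_1490 (32.2-fold) and Synpcc7942_1489 (29.5-fold) were the highest and Synpcc7942_1607 (43.6-fold) and Synpcc7942_2105 (15.8-fold) the lowest. The E335Q dusk libraries of Synpcc7942_1490 held 29740 and 6947, and the E335Q dawn libraries of Synpcc7942_2105 11670 and 206, whose fold was 115 without E335Q dawn replicate 1 and 2.21, not passing, without replicate 2. Without E335Q dusk replicate 1 or 2 the fold was 66.5 or 15.6 for Synpcc7942_1490 and 59.1 or 14.8 for Synpcc7942_1489.

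The count of 81 was 1030 without E335Q dawn replicate 1 (52 higher, 978 lower) and 195 without replicate 2 (112 higher, 83 lower). It was 36, 34, 39 and 32 without relA dawn 1 and 2 and relA dusk 1 and 2, and 28 and 32 without E335Q dusk 1 and 2. The psbAI call was lost as deposited without relA dawn replicate 2 (-1.42), relA dusk replicate 1 or 2 (-1.57 and -1.46) or E335Q dusk replicate 2 (-1.50), and kept on the relative scale in each case. Without E335Q dawn replicate 1 kaiC (-1.08) and kaiB (-0.99) passed, as did kaiA, rpaA, rpaB, sasA, ldpA, rpoD1 and Synpcc7942_1746 (-0.60, -0.78, -0.67, -0.72, -0.82, -0.57 and -0.93) and, on the relative scale, nrtA (-3.60) and Synpcc7942_2105 (-6.32), and without E335Q dawn replicate 2 cikA (0.73) and hpf (1.34). The relative calls were lost for cikA (0.71 to 0.79, without relA dawn replicate 2, relA dusk replicate 1 or 2 or E335Q dusk replicate 1), hpf (1.08 to 1.26, without relA dawn replicate 1 or 2 or relA dusk replicate 1), Synpcc7942_1849 (0.82 to 0.98, without any 1 relA library or E335Q dusk replicate 2), glgB (-0.60 to -0.54, without any 1 relA or E335Q dusk library) and glgC (0.48 to 0.70, without any 1 library other than E335Q dawn replicate 1). The relative glgC call also ended with the replicate block or no trend. With a pseudocount of 10% the folds of Synpcc7942_1607 and Synpcc7942_2105 were over 1.5 times smaller. The relative count was 516 without E335Q dawn replicate 1 and between 143 and 225 without any other library.

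**Figure D5:**
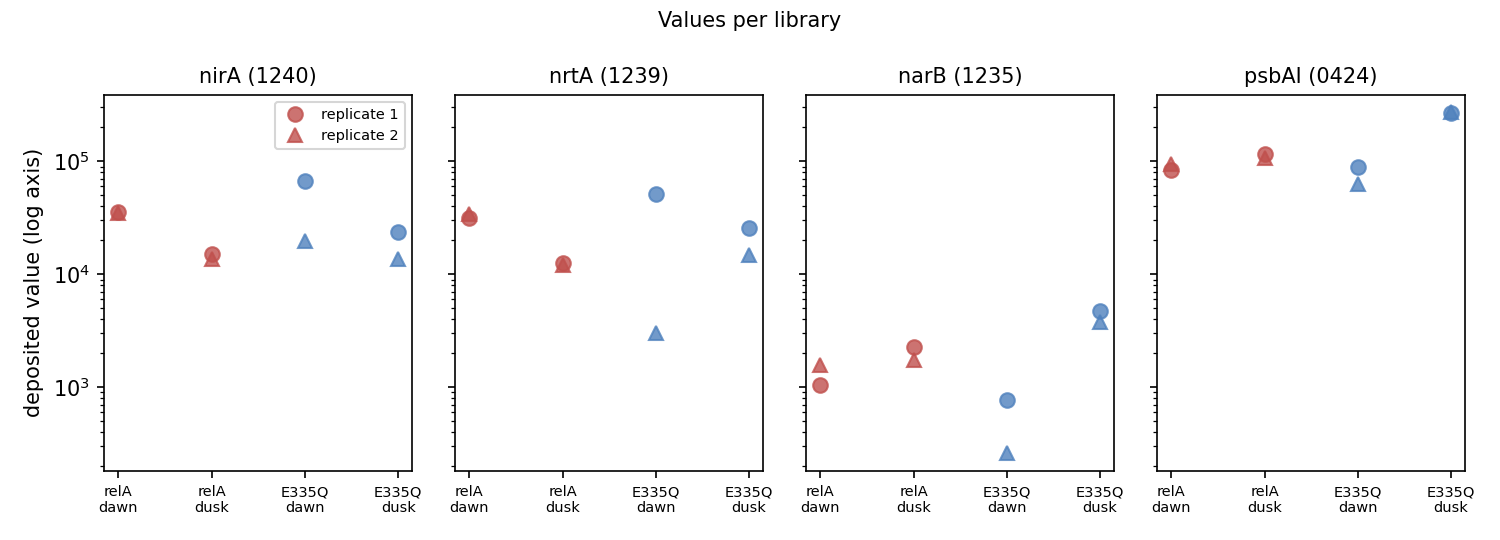
Deposited values (y axis, log scale) of nirA, nrtA, narB and psbAI in each of the 8 libraries (circles replicate 1, triangles replicate 2, red relA, blue E335Q). In each strain narB and psbAI are higher in both dusk libraries than in both dawn libraries, with the larger rise in E335Q. nrtA differs between the E335Q dawn libraries (51444 and 2999).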

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

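The tests of abundant loci, of the factor between reads and values and of nrtA under library scaling were chosen only after the results were seen, and those of low plasmid values and of an exchanged label before theirs. The nrtA test itself replaced a first version over the 6 loci from narB to nirA, which had been run and gave a median gap of 3.15. The change was made after that result and the gaps of the single loci were seen. Over the 3 named loci (nirA, nrtA and narB) the median gap is 1.16, between the limits of 1 and 2 set for the test, and scaling would have stayed undecided. The test of abundant loci replaced the median change without them, which so few loci could not have moved.

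The time change differed between the strains by limma's interaction test at 81 loci as deposited and at 413 relative to the library medians. As deposited these included psbAI (Synpcc7942_0424, -1.52), narB (Synpcc7942_1235, -2.55) and nrtA (Synpcc7942_1239, -2.07). Relative to the medians they included cikA (Synpcc7942_0644, 0.76), hpf (Synpcc7942_2352, 1.20), the sigma factor locus Synpcc7942_1849 (0.95), psbAI (-1.31), glgB (Synpcc7942_1085, -0.57), glgC (Synpcc7942_0603, 0.60) and narB (-2.34). The nitrogen assimilation list passed camera with a median of -0.71 (limma adjusted p = 0.00305), but not with an estimated correlation (adjusted p = 0.985), after centring, or without E335Q dawn replicate 2 (adjusted p = 0.784). The nrtA difference was -0.02 without that library. Entries with no gene name, outside every comparison, held up to 0.0258% of a library's values (E335Q dusk replicate 2).

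The median locus was about 3-fold lower in relA than in E335Q. A few abundant loci taking reads from the others would have to leave the others a far smaller share in relA, but the share outside the 10 highest loci and the structural RNA tags was at most 1.07 times larger in E335Q (1.08 for the most distant pair of libraries), which argues against them. The factor between reads and deposited values stays open. Read depths were alike and the value given to 1 read was 3.09 times higher in E335Q, so the shift lies in that factor, for which the labels name external standards without saying how it was computed. It may reflect the strain, which stays open as untested, the amount of culture or the recovery of standards, and these cannot be told apart without the standards' reads, not analysed here, and the cell number per extraction.

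The 15 plasmid loci tested, of 50 in the table, were less reduced than the chromosome, with relative medians of 1.03 at dawn and 1.35 at dusk. Low values and the pseudocount might compress their change, but with a pseudocount of 0.1% the plasmid medians lay at percentile 100 of 10000 matched chromosomal lists at the lower of both times. The highest matched list reached 0.92 at dawn and 0.76 at dusk against plasmid medians of 1.03 and 1.36. Plasmid loci may vary together, which the matched lists do not allow for. With an estimated correlation camera gave adjusted p = 0.283 and 0.121 by limma. That test used the deposited scale, where library scale shared by all loci enters the correlation. It therefore cannot show whether plasmid loci vary together. On the relative scale limma's fry gave unadjusted p = 1.48e-06 at dawn and 7.83e-07 at dusk, both as higher in relA. As deposited fry gave unadjusted p = 0.675 and 0.998. The strain difference stays open as untested, and plasmid copy number, which DNA reads would give, was not measured here.

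nrtA differed 17.2-fold between the E335Q dawn libraries. At nrtA alone, library scaling leaves most of the gap, since 3.47 on the log2 scale remained after centring, against an SD over all loci of 0.40. The gap was 4.09 before centring and was known when this test was set. Its outcome was therefore fixed in advance and is not independent support. A label exchanged with another group could place a foreign library in this one, but the centred profiles of the pair correlated more with each other than with any other group, by a margin of 0.61. nirA (Synpcc7942_1240, 1.16) and narB (0.87) differed in the same direction after centring. The design gives no biological difference between these libraries, so no biological explanation was tested; further replicates at dawn would show whether nitrate loci vary between cultures.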

How the results depend on the processing

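The relative counts and values, the groups by level, the lists without structural RNA tags, the test over both times and the structural RNA tag list were chosen only after the result was seen. The direction of genotype calls depended on scaling, which by construction removes the shift between libraries. The 2 replicates per group leave 4 residual degrees of freedom, a lone remaining library is assumed to vary like the other groups, and depth was not the limit except for the lowest loci. DESeq2 was planned for whole reads and was not run. The values were whole multiples of a step in each library, but a separate check did not accept that step as a read. Too few values were low enough for that check. The read numbers given here therefore rest on taking the step as a read. Where no cause is given, the cause was not tested.

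Centring called 1162 loci at dawn, 953 at dusk, 1030 for time in relA, 1244 for time in E335Q and 413 for the interaction, and quantile normalization 1028, 970, 1075, 1168 and 342. At both times 523 loci shared a genotype direction after centring (2294 as deposited), and 601 a time direction (224). With the 4 libraries of a comparison alone time in relA had 1048 calls and time in E335Q 256. A 2-fold minimum left 266 calls for time in relA. Relative counts with a 2-fold minimum were 237, 207, 256, 308 and 134, and rises then outnumbered falls at dawn (171 and 66), at dusk (130 and 77), in relA (186 and 70) and in E335Q (214 and 94), against more falls than rises without it. The shift at dusk was -1.44 with a pseudocount of 10%.

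Lists past the threshold numbered 3, 2, 3, 2 and 1 in the same order. With an estimated correlation there were 0 in each comparison, with centring 1 at dusk and 0 in the time comparisons and the interaction, and with quantile normalization 1 at dusk and 0 for time in relA and the interaction. Among lists that passed camera and have no fry result above, limma's fry was run on the relative scale. It gave unadjusted p = 0.0284 for chaperones and 0.00729 for nitrogen at dawn. For photosystem II at dusk fry gave unadjusted p = 0.0140, and for nitrogen in the interaction 0.186.

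Of the 39 loci followed at dawn on the deposited scale, 15 turned sign after centring, kaiB 0.21, kaiC 0.21, rpaA 0.39, rpaB 0.0388, cikA 0.0502, pex 0.68, hpf 0.26, Synpcc7942_1849 0.46, psbDI 0.55, rbcS 0.17, glgP 0.36, zwf 0.19, opcA 0.35, isiA 0.31, ntcA 0.17. Of the 37 followed at dusk 20 did, rpaA 0.17, cikA 0.81, labA 0.0108, pex 0.95, hpf 1.47, Synpcc7942_0672 0.11, psbAI 0.36, psbDI 0.79, rbcL 0.30, rbcS 0.71, glgP 0.37, zwf 0.28, opcA 0.36, isiA 0.71, isiB 0.34, ntcA 0.20, glnA 0.94, narB 0.54, nblA 0.0710, purF 0.12. After quantile normalization 19 turned at dawn, kaiA 0.12, kaiB 0.24, kaiC 0.40, rpaA 0.55, rpaB 0.21, cikA 0.19, pex 0.69, hpf 0.41, rpoD1 0.26, Synpcc7942_1849 0.13, psbDI 0.33, rbcL 0.29, rbcS 0.48, glgC 0.11, glgP 0.48, zwf 0.12, opcA 0.35, isiA 0.22, ntcA 0.32, and 20 at dusk, rpaA 0.23, cikA 0.87, labA 0.0229, pex 1.00, hpf 1.63, Synpcc7942_0672 0.0920, psbAI 0.58, psbDI 0.76, rbcL 0.35, rbcS 0.79, glgB 0.00388, glgP 0.42, zwf 0.32, opcA 0.40, isiA 0.68, isiB 0.18, ntcA 0.20, glnA 0.99, narB 0.57, purF 0.17. Loci outside that selection, such as glgB at dawn, turned as well. psbAII (Synpcc7942_0893) at dawn, relative to the medians, turned to 0.60 with a pseudocount of 10%, and nrtA at dawn was -0.64 without E335Q dawn replicate 2 and 3.45 without replicate 1. The structural RNA tags (relative median) turned to -0.33 at dusk and 0.78 for time in E335Q without E335Q dusk replicate 1, against 0.97 and -0.76 without replicate 2. For the interaction they were at 0.80 without E335Q dusk replicate 2 and -0.78 without replicate 1.

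Leaving out each library in turn gave counts of 2124 to 2525 (dawn), 2379 to 2535 (dusk), 173 to 1057 (time in relA), 271 to 1213 (time in E335Q) and 28 to 1030 (interaction). Relative counts were 750 to 1121, 549 to 1044, 585 to 1113, 965 to 1198 and 143 to 516. The shifts were -1.77 to -1.13, -1.71 to -1.58, -0.19 to -0.08 and -0.28 to 0.39. Shared directions were 2064 to 2461 for genotype and 126 to 600 for time. Lists past the threshold were 3 to 4, 1 to 4, 0 to 4, 0 to 3 and 0 to 3.

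With the replicate number as a block there were 2390, 2506, 456, 539 and 116 calls, and 1127, 916, 982, 1213 and 325 relative to the medians. Among the loci followed as deposited, the block added 2 calls for time in E335Q and 1 for time in relA. With it kaiB at dusk passed as lower in relA relative to the medians, at -0.34. Deviations of same-numbered libraries correlated between -0.38 and 0.15, with both signs, which does not show whether they shared a culture or batch.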

Other observations

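All of the tests in this part were chosen after the result was seen.

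Loci that changed between dusk and dawn in both strains were compared in size. Of 601 loci called in the same direction in both strains relative to the medians, 58.9% had the larger change in E335Q, with a median absolute log2 change of 0.75 in relA and 0.82 in E335Q. The interaction test called 78 of these 601. The fixed pseudocount compresses changes more in relA, whose values are lower, and no other pseudocount was tried for this comparison. Replicates also lay further apart in E335Q, with an SD of their log2 gap over loci of 0.40 at dawn and 0.31 at dusk. In relA it was 0.26 and 0.23. A larger amplitude in E335Q is therefore not shown.

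The structural RNA tags, taken by tag because the planned list of ribosomal and transfer RNA needed product names, differed between the libraries of a group. After centring their median was 2.89-fold higher in E335Q dusk replicate 2 than in replicate 1, and all 32 were higher there. In the other groups the median differed 1.60-fold (relA dawn), 1.12-fold (relA dusk) and 1.46-fold (E335Q dawn).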
